A study of Mus musculus with 10 samples.

How the data were processed

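Liver RNA of 5 groups of male mice was measured on the Affymetrix MG_U74Cv2 array. Each group was 1 pool of RNA from 5 mice, and each pool (20 µg) was hybridised to 2 arrays, giving 10 arrays. Per the submitters' processing notes the deposited values were made with RMA, which corrects background, normalises across arrays and summarises the probes of a probe set; no version is given. The series' design text names Microarray Suite 5.0 for the original processing. The deposited values were taken as log2 expression per probe set, from their range of 2.17 to 13.3 and the near-equal medians of the arrays, and were not transformed further. Microarrays give no counts, and their number limits the precision.

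The deposited table holds 11934 probe sets. The 66 control probe sets whose names begin with AFFX were left out of the tests, and 11868 were tested. The platform's annotation names 1 gene for 7717 of them, several for 150 and none for 4001, and 5928 genes were measured. Of the Entrez identifiers, 7699 matched the mouse RefSeq annotation. It was used for gene names and, through chromosome and start position, for the order of neighbouring genes only. Where several probe sets carry a gene's name, the one with the highest mean over the 10 arrays stands for the gene, and the values of the others are given beside a named gene. Of the tested probe sets, 4380 (36.9%) carry a suffix other than plain _at. Most of them carry _r_at (1829) or _i_at (1307). The suffixes _f_at (1091) and _s_at (122) mark probes that may match more than 1 transcript.

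Groups were compared with limma 3.58.1 in R 4.3.3. A single fit (lmFit and eBayes) held all 10 arrays and the 5 groups, with 5 residual degrees of freedom and 6.26 prior ones. Tests were two-sided with Benjamini-Hochberg adjustment over the tested probe sets within each comparison. A probe set was called at an adjusted p under 0.05 together with a difference of at least 1.5-fold. The fold floor was added because the residual spread is that between hybridisations of a pool and holds no variation between mice. The 4 comparisons of the report were Scap-/- with Scap wild type, TgSREBP-1a and TgSREBP-2 each with SREBP wild type, and the transgenics with each other. Scap wild type was compared with SREBP wild type in the closing section alone, since diet, age, injections, strain and study differ between them.

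Overlaps between comparisons were set beside the counts expected of independent lists and of 100 simulated sets of unchanged groups sharing the wild type, and tested with Fisher's exact test. Relations of effects are Pearson correlations across probe sets. Gene lists, 24 of them, were tested with camera at a correlation of 0.01, with adjustment over the 20 lists with at least 3 measured genes, and again with an estimated correlation. The other 4 lists had 0 to 2 measured genes and were not tested. The median of each list was ranked among 10000 random lists of the same size and level. Lists of pancreatic acinar and skeletal muscle markers were added after the values were seen, the former tested without Cpa1, Gp2 and Cuzd1, and their p-values are not adjusted.

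Named genes followed a rule. In each comparison these were the 10 largest increases and 10 largest decreases among called probe sets with 1 gene symbol and no overlap between the groups' arrays, leaving out clone and predicted gene names. To them were added up to 10 called members of the fixed lists, genes raised in both transgenics and lowered in Scap-/-, and the largest increase and decrease without a gene name. A further fixed set of genes was to be named wherever measured, but none of them has a tested probe set. The tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

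Each result was recomputed under quantile normalisation, median centring, brighter probe sets alone, plain _at probe sets alone, a variance trend, robust variance, no fold floor, a 2-fold floor, limma's treat against 1.2-fold, arrays of the same study alone, a replicate block, and without each array in turn. Gene lists were also tested with the mean over the probe sets of a gene. Cyclic loess, the 18S rRNA signal as a covariate, a crossed replicate pairing and counts without the acinar genes were added after the data were seen. An alternative pseudocount was not run because the values are on the log2 scale.

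The procedure was tested on simulated data of the same size in which 50 probe sets changed at each fold. It called 48% of those changed 1.5-fold, 98% at 2-fold and 100% at 3-fold and 4-fold, with 4 false calls among unchanged probe sets and 0 with the wrong sign. In the simulated Scap comparison, where nothing changed, 1 probe set was called. With camera, a list of 13 genes shifted by 0.5 was called, and 2 of 100 unshifted lists had a p under 0.05. The simulated genes varied independently of each other and with the spread between hybridisations alone. These rates therefore do not cover lists of correlated genes or variation between mice. Figures were drawn with matplotlib 3.10.9.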

Results

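Liver gene expression was measured on Affymetrix U74Cv2 mouse oligonucleotide arrays in 5 groups of male mice. The question behind the design was which genes respond to the sterol regulatory element-binding proteins (SREBPs), transcription factors that switch on the synthesis of cholesterol and fatty acids. TgSREBP-1a and TgSREBP-2 mice carry a transgene for the active nuclear form of the human protein. They and wild-type littermates, here called SREBP wild type, were 12 to 16 weeks old and had been fed for 2 weeks on a diet rich in protein and poor in carbohydrate. Scap-/- mice lack SCAP in the liver, the escort protein without which SREBPs are not processed to their nuclear form. They and the Scap wild type mice were 10 to 12 weeks old, ate chow and had been given 4 injections of poly(I:C), which turns on the Cre recombinase, the last 14 days before the livers were taken. Each group was represented by 1 pool of RNA from 5 mice, hybridised to 2 arrays. The limma p-values therefore measure the spread between hybridisations of a pool. Those of the overlap and sign tests were computed across probe sets or genes, and camera sets a list's genes against the other genes. All of them compare pools, not mice.

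The median signal of the 10 arrays lay between 4.69 and 4.77 on the log2 scale. Across probe sets, which are not independent replicates, duplicate arrays correlated at 0.992 to 0.995, and 6 of the 10 arrays correlated more closely with an array of another group than with their duplicate. The signal of the 18S ribosomal RNA control differed between duplicates, from 7.19 in replicate 1 to 9.16 in replicate 2 of TgSREBP-1a and from 8.03 to 8.21 in Scap wild type. The number of arrays limits the precision, and the median standard error of a log2 difference between groups was 0.114. The deposited values carry no detection calls, so whether a low signal lies above background is not known. Differences against such signals are given without a fold, since that of the transcript may be larger: Dnaic1 (3.46), Lce3f (3.20) and Defb4 (2.95) in Scap wild type, Plekhd1 (3.38), Cyp2c55 (3.50) and Cuzd1 (3.84) in SREBP wild type, Plekhd1 (3.56) in TgSREBP-2 and Cuzd1 (3.18) in TgSREBP-1a. No tested probe set is named for Scap, Srebf1 or Srebf2, so neither the deletion nor the transgenes were checked at their own transcripts.

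Without SCAP, 3 genes of cholesterol synthesis were lower in the liver pool. Nsdhl, a sterol dehydrogenase of the later part of the pathway, had a level of 7.53 ± 0.56 in Scap-/- and 10.00 ± 0.34 in Scap wild type (log2, mean ± SD, n = 2 hybridisations). That was a 5.53-fold difference (log2 difference -2.47, SE 0.279, limma adjusted p = 0.00623). Tm7sf2, a sterol reductase, was 3.56-fold lower (log2 difference -1.83, SE 0.233, adjusted p = 0.00963). Pmvk, phosphomevalonate kinase, was 3.32-fold lower (log2 difference -1.73, SE 0.165, adjusted p = 0.00149), while the second Pmvk probe set differed by -0.04. Of the 13 measured members of the cholesterol biosynthesis list, 3 fell, none rose and 10 did not pass the test, and 3 fell when adjusted over the list alone. Among those that did not pass, Cyp51 differed by -0.32, Sc5d by -0.31, Lss by -0.22 and Fdps by 0.24. The signal of Sc5d was low on the Scap arrays (3.03 to 3.41), so its value says little. The list as a whole was lower than other genes (camera adjusted p = 2.51e-05; adjusted p = 0.234 with an estimated correlation). The pancreatic acinar transcript Cpa1 differed between the same pools by -2.86.

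None of the 5 measured members of the fatty acid and triglyceride synthesis list passed the test over all probe sets in Scap-/-, and 1 did when adjusted over the list alone. The largest difference was that of Fads2, a desaturase of polyunsaturated fatty acid synthesis (log2 difference -1.19, SE 0.252, adjusted p = 0.373). The list was lower than other genes (adjusted p = 0.0159; adjusted p = 0.234 with an estimated correlation). The fatty acid oxidation and ketogenesis list had 5 measured members, Hadhb, Hsd17b4, Plin2, Vnn1 and Fgf21. They ranged from 0.10 for Hadhb to 0.28 for Fgf21, none of them called. That list was higher than other genes (adjusted p = 0.0403, and adjusted p = 0.256 with an estimated correlation). No member of the fixed lists of cell type markers was called in this comparison. The adjusted p of the list test was 0.757 for the 5 macrophage and Kupffer cell markers and 0.171 for the 9 endothelial markers.

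Over all 11868 probe sets, 5 were higher and 5 lower in Scap-/-, against 451 at an unadjusted p under 0.05. Those 451 are a smaller share than the 0.05 that unchanged probe sets would give. The arrays of the groups lay apart at 29.7% of probe sets, against 33.3% by chance. The remaining lower probe sets were those of Cpa1, a carboxypeptidase of pancreatic acinar cells (7.25-fold, log2 difference -2.86, SE 0.198, adjusted p = 0.000152), and Gp2, a zymogen granule membrane protein of the same cells (log2 difference -1.32, adjusted p = 0.00783). Higher were Dnaic1, a dynein intermediate chain of cilia (log2 difference 1.63, adjusted p = 0.00136), Lce3f (1.61), the defensin Defb4 (0.87) and the epithelial keratin Krt4 (0.84). A probe set of Ifi27l2b, 165944_at, was also higher (0.96) and is named here after its value was seen, and a brighter probe set of Ifi27l2b differed by 0.07. The count fell to 3 without Scap wild type replicate 1, to 6 without Scap wild type replicate 2 or Scap-/- replicate 1, to 4 when only the Scap arrays were fitted or with plain _at probe sets alone, and to 6 with treat, and it was 19 with the replicate number as a block. Nsdhl lost its call without Scap wild type replicate 1 (log2 difference -2.22, adjusted p = 0.101) and in the fit of the Scap arrays alone (adjusted p = 0.0719, with Gp2, Krt4, Defb4 and Lce3f losing theirs there too at 0.117, 0.149, 0.167 and 0.365), Tm7sf2 without Scap-/- replicate 2 (-1.61), Scap wild type replicate 1 (-1.74) or replicate 2 (-1.93), and Gp2 without Scap-/- replicate 2 (-1.14) or Scap wild type replicate 1 (-1.17). Lce3f, Defb4 and Krt4 lost theirs without Scap-/- replicate 1, Scap wild type replicate 1 or Scap wild type replicate 2, Krt4 also without Scap-/- replicate 2 and Lce3f also without either array of SREBP wild type or of TgSREBP-1a, with log2 differences over all alternatives of 1.16 to 2.05, 0.76 to 0.97 and 0.77 to 0.91. Pmvk, Cpa1 and Dnaic1 kept theirs on leaving out each of the 10 arrays.

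**Figure D1:**
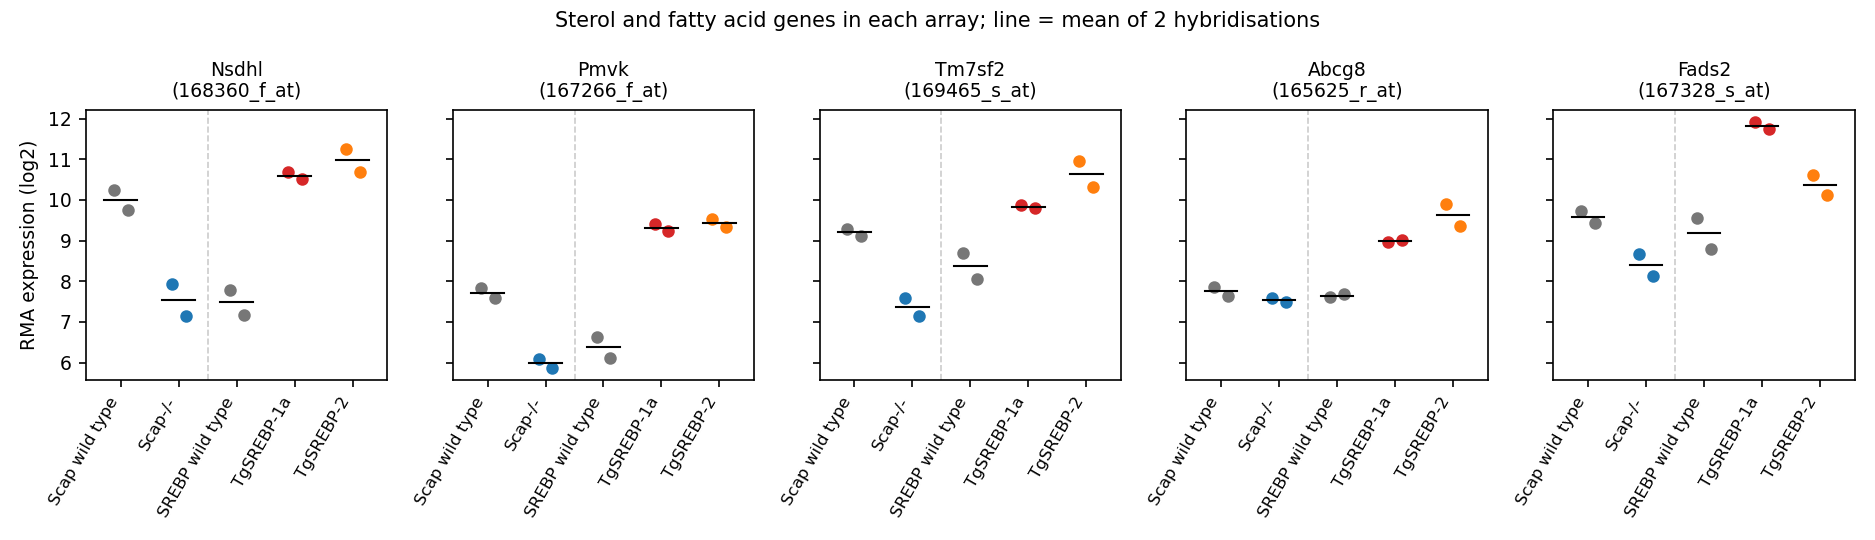
RMA expression (log2) of Nsdhl, Pmvk, Tm7sf2, Abcg8 and Fads2 on each of the 10 arrays, with points for single hybridisations, black lines for the mean of the 2 hybridisations of a group, and a dashed line between the Scap and SREBP groups. Nsdhl lay at 7.53 in Scap-/- against 10.00 in Scap wild type, and at 10.60 in TgSREBP-1a and 10.98 in TgSREBP-2 against 7.48 in SREBP wild type.

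The same genes of cholesterol synthesis were higher in the TgSREBP-1a pool than in SREBP wild type. Nsdhl rose 8.67-fold, from 7.48 ± 0.43 to 10.60 ± 0.12 (log2, n = 2 hybridisations; log2 difference 3.12, SE 0.279, adjusted p = 0.000192). Pmvk rose 7.64-fold (log2 difference 2.93, SE 0.165, adjusted p = 4.12e-06; 0.03 at the second Pmvk probe set) and Tm7sf2 2.74-fold (log2 difference 1.45, SE 0.233, adjusted p = 0.0104). Of the 13 measured cholesterol genes, 3 rose, none fell and 10 did not pass the test, and 4 rose when adjusted over the list alone. Lss differed by 0.51 (adjusted p = 0.0388), under the 1.5-fold floor, while Cyp51 at 0.69, Sc5d at 0.41 and Fdps at -0.55 had adjusted p-values of 0.163, 0.18 and 0.139. The signal of Sc5d was low in these pools too (2.98 to 3.55). The list was higher than other genes (adjusted p = 1.25e-06; adjusted p = 0.173 with an estimated correlation). Abcg8, part of the transporter that moves sterols out of hepatocytes into bile, rose 2.55-fold (log2 difference 1.35, SE 0.155, adjusted p = 0.0012) and was the 1 called member of the 5 measured genes of sterol uptake and SREBP control (list adjusted p = 0.0672). The acinar transcript Cpa1 differed between the same pools by -4.39.

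In the fatty acid and triglyceride synthesis list, Fads2 rose 6.25-fold in TgSREBP-1a, from 9.18 ± 0.54 to 11.83 ± 0.12 (log2 difference 2.64, SE 0.252, adjusted p = 0.000275). The other 4 measured members, Dgat1, Hsd17b12, Lpin1 and Acly, lay between -0.10 and 0.12. The signal of Acly was low on the arrays of these pools (3.24 to 3.42), so its value says little. The list's mean was 0.50 and its median -0.07, so that they differ in sign, and the list test gave adjusted p = 0.376. The hepatic hormone Fgf21 fell 1.61-fold (log2 difference -0.69, SE 0.104, adjusted p = 0.00784) and Klb, the co-receptor for that hormone, fell 2.12-fold (log2 difference -1.08, SE 0.103, adjusted p = 0.000275). Fgf21 was the 1 called member of the 5 measured in the fatty acid oxidation and ketogenesis list (list adjusted p = 0.942). It was also the 1 called of 6 in the list of ER stress and unfolded protein response (list adjusted p = 0.942). The glutathione transferase Gstm1 rose 1.74-fold at probe set 137229_f_at, while 2 further probe sets of the gene differed by -0.27 and 0.06. Of the 5 measured macrophage and Kupffer cell markers, 2 rose, namely Vsig4, a complement receptor of Kupffer cells (2.2-fold, adjusted p = 0.0185), and Laptm5 (2.06-fold, adjusted p = 0.00538). That list was higher than other genes (adjusted p = 0.006; adjusted p = 0.173 with an estimated correlation). Lgals3bp rose 1.80-fold and was the 1 called member of the 13 measured interferon response genes, a list with a median of -0.02, a mean of 0.09 and adjusted p = 0.429. Epcam fell (log2 difference -0.63) among the 4 measured bile duct cell markers and is named after its value was seen.

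The 2 largest increases in TgSREBP-1a lay outside the lists. Plekhd1, a gene with a pleckstrin homology domain, rose from 3.38 ± 0.15 to 7.92 ± 0.19 (log2 difference 4.54, SE 0.124, adjusted p = 5.22e-09). H2-Q2, a class I histocompatibility gene, rose 8.94-fold, from 5.97 ± 0.09 to 9.13 ± 0.20 (log2 difference 3.16, SE 0.148, adjusted p = 7.4e-07). Lactb2 (log2 difference 1.91), the unnamed probe set 135538_at (1.86), Dynlt3 (1.84), Cyp2c55 (1.68), Fyb2 (1.62) and Cyb5b (1.61), a mitochondrial cytochrome b5, followed, though 2 further Dynlt3 probe sets differed by -0.04 and -0.27 and a second one of Cyb5b by 0.26. The largest decrease was that of the acinar gene Cpa1, from 9.89 ± 0.51 to 5.49 ± 0.16 (21-fold, log2 difference -4.39, SE 0.198, adjusted p = 7.04e-07), and Gp2 and Cuzd1 of the same cells fell as well (-1.48 and -0.66). Sdr9c7, a short-chain dehydrogenase, fell 6.44-fold (log2 difference -2.69, SE 0.205, adjusted p = 5.47e-05), and the unnamed probe set 171596_at fell 4.45-fold. Slc9a4 (-1.67), Serpina11 (-1.51), Kirrel3 (-1.40), Nat8 (-1.34), the interleukin-1 co-receptor gene Il1rap (-1.33) and Prl5a1 (-1.24) also fell, while the second Il1rap probe set differed by -0.08.

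In all, 81 probe sets were higher and 42 lower in TgSREBP-1a, against 1115 at an unadjusted p under 0.05. The count was 40 without TgSREBP-1a replicate 1, 57 without TgSREBP-1a replicate 2 and 63 without SREBP wild type replicate 2. It was 67 with plain _at probe sets alone, 59 with a 2-fold floor, 47 with treat and 186 with the replicate number as a block. Under the same 3 omissions Tm7sf2 lost its call (1.41, 1.49 and 1.13), as did Vsig4 (1.12, 1.16 and 0.86), and without TgSREBP-1a replicate 1 or SREBP wild type replicate 2 so did Laptm5 (0.99 and 0.87) and Fgf21 (-0.56 and -0.67). Lactb2, Dynlt3 and Lgals3bp lost theirs under those 3 omissions, and Dynlt3 and Lgals3bp also without either TgSREBP-2 array, Lgals3bp without either Scap wild type array too (range over all alternatives 1.36 to 2.47, 1.45 to 2.22 and 0.58 to 1.12). Cyp2c55, Cyb5b and Il1rap lost theirs without any 1 of the 4 arrays compared, and Il1rap also without either TgSREBP-2 array (1.57 to 1.80, 1.38 to 1.85 and -1.53 to -1.13). Slc9a4 lost its call without SREBP wild type replicate 1 or either TgSREBP-1a array, Prl5a1 without SREBP wild type replicate 1 or TgSREBP-1a replicate 2, Nat8 without TgSREBP-1a replicate 2, and Kirrel3 and Gstm1 without TgSREBP-1a replicate 1 (-2.10 to -1.23, -1.45 to -1.02, -1.59 to -1.09, -1.72 to -1.09 and 0.73 to 0.86). Nsdhl, Pmvk, Fads2, Abcg8, Fyb2, 135538_at, Plekhd1, H2-Q2, Klb, Serpina11, 171596_at, Sdr9c7, Gp2 and Cpa1 kept their calls on leaving out each of the 10 arrays.

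In the TgSREBP-2 pool, too, genes of cholesterol synthesis were higher than in SREBP wild type. Nsdhl rose 11.3-fold, from 7.48 ± 0.43 in SREBP wild type to 10.98 ± 0.40 (log2 difference 3.50, SE 0.279, adjusted p = 0.000171). Pmvk rose 8.30-fold (log2 difference 3.05, SE 0.165, adjusted p = 5.31e-06; 0.14 at the second Pmvk probe set), Tm7sf2 4.81-fold (log2 difference 2.27, SE 0.233, adjusted p = 0.00151) and Abcg8 3.97-fold (log2 difference 1.99, SE 0.155, adjusted p = 0.000171). Of the 13 measured cholesterol genes, 3 rose, none fell and 10 did not pass the test, and 4 rose when adjusted over the list alone. Cyp51, lanosterol demethylase, differed by 1.14 (adjusted p = 0.0575). The list was higher than other genes (adjusted p = 4.61e-09; adjusted p = 0.125 with an estimated correlation). The acinar transcripts Cuzd1, Gp2 and Cpa1 differed between the same pools by 1.12, 1.08 and 0.78. Fads2 differed by 1.18 and did not pass (adjusted p = 0.211), while Fads3, a related gene of the desaturase family, rose 2.44-fold at one probe set (log2 difference 1.29, SE 0.13, adjusted p = 0.00151) and differed by -0.15 at another.

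Further increases in TgSREBP-2 were those of 135538_at (5.09-fold), Cyp2c55 (log2 difference 1.86), the amino acid transporter subunit Slc3a1 (2.81-fold), the kinase gene Sik1 (2.23-fold), the interferon regulatory factor Irf7 (2.19-fold) and the lipopolysaccharide-binding protein gene Lbp (1.92-fold). Irf7 was the 1 called member of the 13 measured interferon genes (list adjusted p = 0.0581), and 2 rose when adjusted over the list alone. None of the 5 macrophage markers was called, with Vsig4 at 0.74 and Laptm5 at 0.54, and that list was higher than other genes (adjusted p = 0.0424; adjusted p = 0.331 with an estimated correlation). The acinar gene Cuzd1 rose (log2 difference 1.12, adjusted p = 0.00151) and Gp2, named after its value was seen, rose by 1.08 (adjusted p = 0.0273), while Cpa1 differed by 0.78 without a call. Ugt2b38 had the only lower probe set, 137211_i_at (log2 difference -1.81), which is named after its value was seen, and a second probe set of Ugt2b38 differed by -0.41. In all, 13 probe sets were higher and 1 lower, against 752 at an unadjusted p under 0.05. The count was 37 with the replicate number as a block, 22 with the 18S rRNA signal as a covariate, 9 with treat and 4 with plain _at probe sets alone. It was 7 without TgSREBP-2 replicate 1 and 9 without SREBP wild type replicate 2, and Irf7, Cyp2c55 and Lbp lost their calls without any 1 of the 6 arrays of that study, with log2 differences over all alternatives of 1.05 to 1.21, 1.80 to 1.92 and 0.84 to 1.04. Lbp lost its call also without either Scap wild type array, and Sik1 without SREBP wild type replicate 1 (1.21), SREBP wild type replicate 2 (1.10) or TgSREBP-2 replicate 1 (0.99). Slc3a1 lost its call without SREBP wild type replicate 2 (1.31), TgSREBP-2 replicate 1 (1.51) or replicate 2 (1.47).

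**Figure D2:**
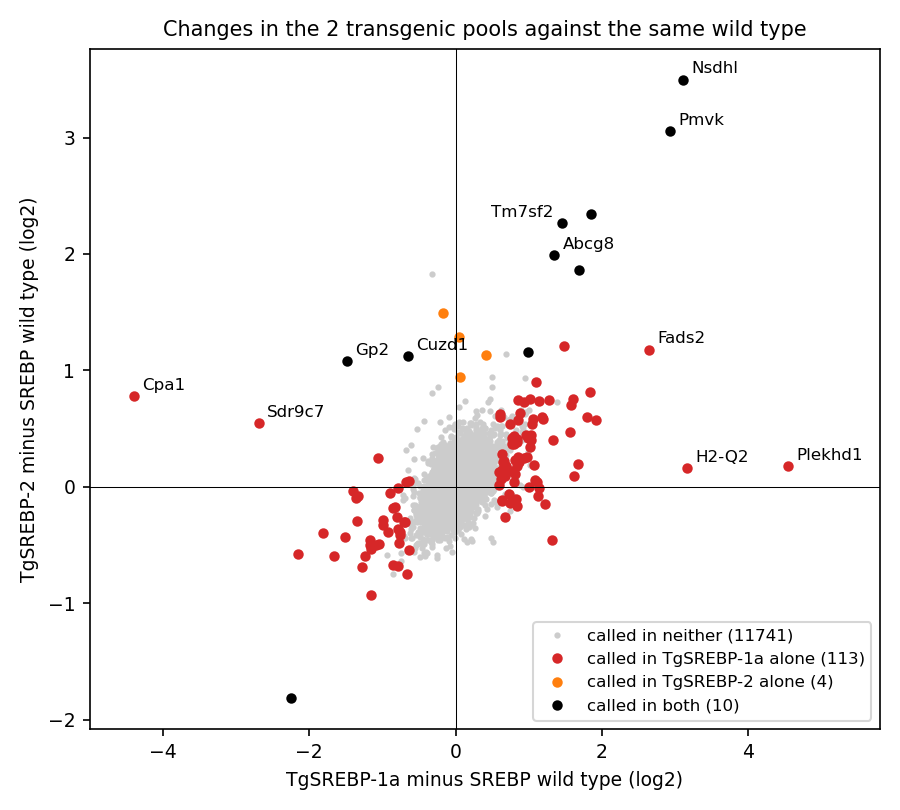
Log2 difference from SREBP wild type of each of the 11868 probe sets in TgSREBP-1a (horizontal axis) and in TgSREBP-2 (vertical axis), coloured by where the probe set was called, with 10 called in both, 113 in TgSREBP-1a alone and 4 in TgSREBP-2 alone. Nsdhl and Pmvk lie at the upper right, Plekhd1 (4.54) and H2-Q2 (3.16) lie along the horizontal axis, and Gp2 and Cuzd1 lie on opposite sides of 0 in the 2 pools.

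The direct comparison of the transgenic pools asked how the effects of SREBP-1a and SREBP-2 differ, and in it the shared wild type cancels. Fads2 was 2.76-fold higher in TgSREBP-1a, at 11.83 ± 0.12 against 10.36 ± 0.36 (log2 difference 1.47, SE 0.252, adjusted p = 0.026). Of the 13 cholesterol genes, none was called, with Tm7sf2 at -0.81, Cyp51 at -0.45, Nsdhl at -0.38 and Pmvk at -0.12, and the list test gave adjusted p = 0.514. The fatty acid and triglyceride synthesis list had a median of -0.00415 and a mean of 0.27, which differ in sign (adjusted p = 0.499). Higher in TgSREBP-1a were Plekhd1 (log2 difference 4.36), H2-Q2 (8.02-fold), Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (3.45-fold), Fyb2 (2.89-fold), the oestrogen sulphotransferase Sult1e1 (2.58-fold), Abca5 (2.22-fold), the pantetheinase Vnn1 (1.98-fold) and the endothelial list member Dnase1l3 (1.89-fold). Lower in TgSREBP-1a were Sdr9c7 (9.41-fold), Slc3a1 (3.15-fold), Kirrel3 (2.57-fold), Fads3 (2.36-fold, with 0.20 at its second probe set), the liver protein gene Smlr1 (2.2-fold), Serpina11 (2.11-fold), Nat8 (2.06-fold) and Lbp (1.84-fold). Lbp was the 1 called member of the 7 measured acute phase and complement genes, and that list was lower in TgSREBP-1a (adjusted p = 0.044; adjusted p = 0.577 with an estimated correlation).

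Pancreatic acinar transcripts separated these pools as well. Cpa1 was 36.1-fold lower in TgSREBP-1a than in TgSREBP-2, at 5.49 ± 0.16 against 10.67 ± 0.25 (log2 difference -5.18, SE 0.198, adjusted p = 1.15e-07). Gp2 was 5.90-fold lower, and Cuzd1 was lower by 1.78 on the log2 scale. In all, 32 probe sets were higher and 29 lower in TgSREBP-1a than in TgSREBP-2, against 919 at an unadjusted p under 0.05. The count was 36 with plain _at probe sets alone, 31 with a 2-fold floor, 27 with treat, 96 with the replicate number as a block and 111 with a crossed pairing of the replicates (94 in the same 4 arrays without it). Without TgSREBP-1a replicate 1, TgSREBP-1a replicate 2, TgSREBP-2 replicate 1 or TgSREBP-2 replicate 2 the count was 23, 35, 30 and 38, and Fads2 lost its call each time (log2 difference 1.38, 1.55, 1.72 and 1.21). Lbp, Nat8 and Dnase1l3 also lost theirs without any 1 of these 4 arrays, and Dnase1l3 without either SREBP wild type array (range over all alternatives -0.92 to -0.84, -1.17 to -0.92 and 0.75 to 1.09). Smlr1 lost its call without the first 3 of them (-1.34 to -0.93), Abca5 and Kirrel3 without replicate 1 of either transgenic (0.98 to 1.32 and -1.51 to -1.22), and Vnn1 without replicate 2 of either (0.78 to 1.19). Plekhd1, H2-Q2, Ppp1r3g, Fyb2, Sult1e1, Serpina11, Fads3, Slc3a1, Sdr9c7, Cuzd1, Gp2 and Cpa1 kept theirs on leaving out each of the 10 arrays.

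**Figure D3:**
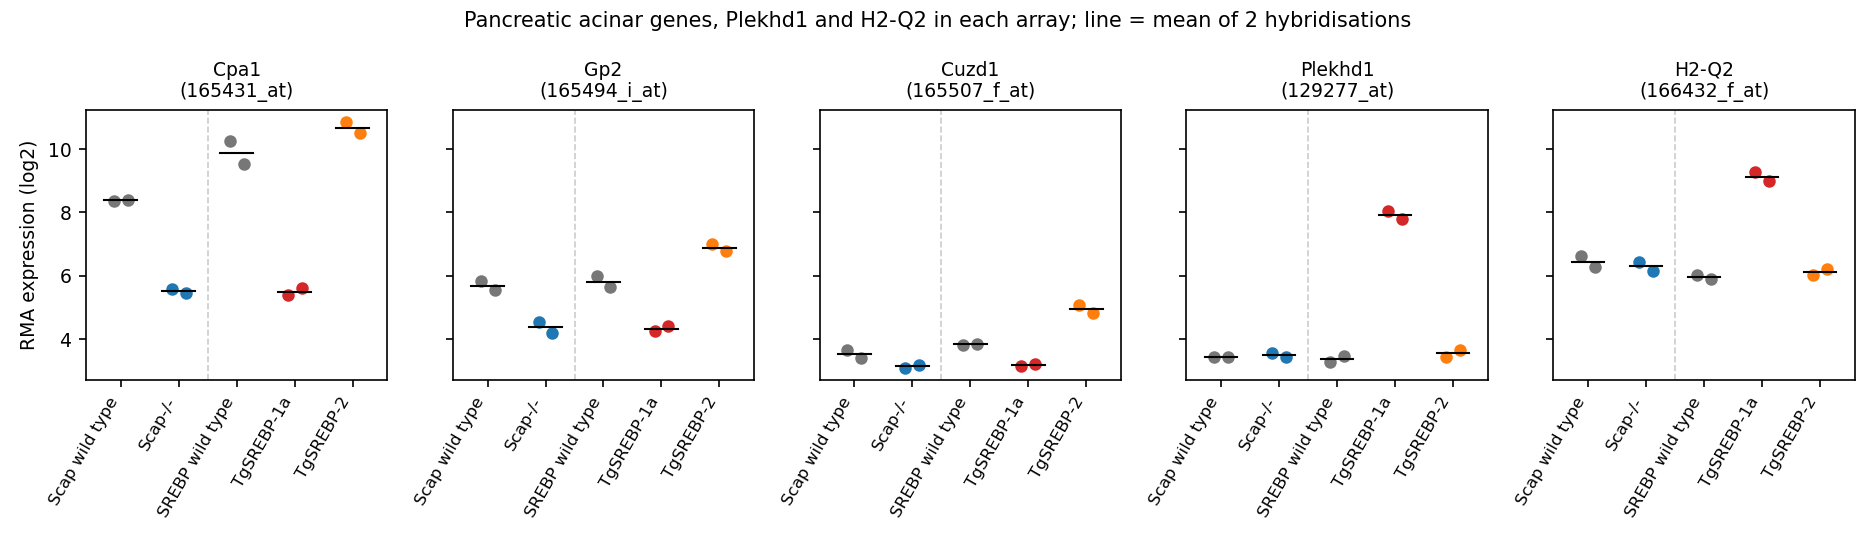
RMA expression (log2) of the acinar genes Cpa1, Gp2 and Cuzd1 and of Plekhd1 and H2-Q2 on each of the 10 arrays, with points for single hybridisations, black lines for the mean of the 2 hybridisations of a group, and a dashed line between the Scap and SREBP groups. Cpa1 lay at 5.52 in Scap-/- and 5.49 in TgSREBP-1a, and at 8.38, 9.89 and 10.67 in Scap wild type, SREBP wild type and TgSREBP-2, while Plekhd1 stood at 7.92 in TgSREBP-1a.

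The combined design asked which genes rise with both transgenes and fall without SCAP, and 3 genes did so, namely Nsdhl, Pmvk and Tm7sf2. The 7 probe sets raised in both transgenics were theirs and those of Abcg8, Cyp2c55, Sik1 and 135538_at, where independent lists would share 0.0887 and simulated unchanged groups against the same wild type shared 0.01 on average. The simulation holds the spread between hybridisations alone, so it does not say what unchanged pools of other mice would share. With 2 wild-type arrays the controls were not split, so part of that excess may come from the shared controls. Of these 7, 3 were among the 5 lowered in Scap-/-, which share no arrays with them, against 0.00295 for independent lists (Fisher's exact test across probe sets, two-sided, p = 1.26e-09). Abcg8 differed by -0.21 in Scap-/- and was not called. In the opposite direction, 1 probe set was lowered in both transgenics, that of Ugt2b38, and it was not raised in Scap-/- (-0.25). The count of 3 fell to 1, Pmvk, without Scap wild type replicate 1, and it was 0 with plain _at probe sets alone, since those of the 3 genes are of the _f_at and _s_at kinds that may match several transcripts.

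Across the 11868 probe sets, which are not independent replicates, log2 differences in TgSREBP-1a and TgSREBP-2 correlated at 0.533, where simulated unchanged groups sharing the wild type gave 0.501. The covariance was 0.0189 against a simulated 0.00805, a difference of 0.0109. This simulation too holds the spread between hybridisations alone, so that a wild-type pool differing from other mice could give such a difference with no effect of the transgenes. With the Scap-/- differences, the correlation was 0.057 for TgSREBP-1a and -0.0443 for TgSREBP-2. For TgSREBP-1a it became -0.0761 without Scap-/- replicate 1 and -0.0498 without Scap wild type replicate 2, and for TgSREBP-2 it became 0.0604 without Scap-/- replicate 2 and 0.0326 without Scap wild type replicate 1.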

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

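The list tests of acinar and muscle markers and the tests of pancreatic tissue in the pools and of a single direction of SREBP activity, in each form, were chosen only after the result was seen, and in the test of shared probes the comparison with plain probe sets was added after its result was seen. The items here differed between the transgene effects in the direct test of TgSREBP-1a against TgSREBP-2, with log2 differences given as TgSREBP-1a minus TgSREBP-2 and 2 hybridisations of 1 pool in each group.

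The pancreatic acinar genes Cpa1 (-5.18), Gp2 (-2.56) and Cuzd1 (-1.78) were lower in TgSREBP-1a. The list of acinar markers, written after the values had been seen, has 14 measured members, 0 of them in another fixed list and 6 above the array median in TgSREBP-1a. Its 11 members other than Cpa1, Gp2 and Cuzd1, which prompted it, include Reg2, itself called lower in TgSREBP-1a than in TgSREBP-2. These 11 were lower in TgSREBP-1a than in TgSREBP-2 (camera p = 6.84e-06, and p = 0.0156 with an estimated correlation). They were higher in TgSREBP-2 than in SREBP wild type (camera p = 0.000742, and p = 0.043 with an estimated correlation). They did not pass camera in Scap-/- (camera p = 0.0614; p = 0.195 with an estimated correlation) or in TgSREBP-1a against SREBP wild type (camera p = 0.0611; p = 0.195 with an estimated correlation), while no skeletal muscle marker was called (p = 0.257 to 0.888 in these comparisons).

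A single direction of SREBP activity would give opposite signs in Scap-/-, where that activity is lost, and in TgSREBP-1a, where it is added. Cpa1 and Gp2 were instead called lower both in Scap-/- (-2.86 and -1.32) and in TgSREBP-1a (-4.39 and -1.48). The mean of all 14 members was -0.4063 in Scap-/- and -0.57 in TgSREBP-1a. These values do not decide the question, because Cpa1 and Gp2 were seen before the test was chosen and each group was 1 pool. For the 11 members other than Cpa1, Gp2 and Cuzd1 a single direction stays open as well, with means of -0.1017 and -0.13 (exact sign-flip tests across genes, two-sided, p = 0.172 and 0.00293). Those tests take genes measured in the same pools as independent. Different amounts of pancreatic tissue taken with the livers may account for the pattern. Of those 11 members, 10 (90.9%) were lower in TgSREBP-1a than in TgSREBP-2 (exact sign test, two-sided, p = 0.0117), but their median difference was -0.22. This sign test does not settle it, because it takes genes of the same pools as independent. It also counts members that read low, and Reg2, which was itself called lower. A first form of this test, on the 10 members not called in that comparison (90% lower), decides nothing, because 2 of them, Ctrc and 2210010C04Rik, have another probe set that was called lower. Of the others, Reg2 (-1.02), Ctrc (-0.60) and Cela2a (-0.57) went with it, Pla2g1b differed by -0.17 (-0.39 at a second probe set) and Ptf1a by -0.05, 2210010C04Rik differed by -0.12 at its brightest probe set and by -1.31 at another, also called lower against SREBP wild type, and Cpb1, Amy2a5, Pnliprp1, Tmed6 and Rbpjl, whose signals in TgSREBP-2 ranged from 2.97 to 3.50, read too low to say much; an effect of genotype that differs between SREBP-1a and SREBP-2 was not tested.

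Plekhd1 (4.36) and H2-Q2 (3.0) were higher in TgSREBP-1a than in TgSREBP-2, and were also called against SREBP wild type. A linked interval around Plekhd1 that differs in TgSREBP-1a could not be decided, because 8 of 40 neighbouring genes were measured, under the 10 needed, and 0 of them changed 1.5-fold; the largest, Plekhd1os, differed by 0.51 (adjusted p = 0.022). A difference across the H2 (MHC) region in TgSREBP-1a could not be decided either, with 1 other H2- gene measured, H2-Aa at -0.04, and 0 changed 1.5-fold. These explanations and an effect of the transgene itself cannot be told apart here.

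Calls in TgSREBP-1a concentrated in probe sets with the _f_at suffix, of which 39 of 1091 (3.57%) were called against 59 plain _at probe sets (0.788%). Higher signal of the _f_at probe sets is argued against as the whole cause, since within strata of mean signal the odds ratio was 3.915 (95% interval 2.58 to 5.95) against 4.67 without that division. Probes shared between related transcripts stay open. Of 17 genes called through an _f_at probe set that have another probe set, 4 had that other one changed the same way. Of 17 called plain probe sets whose gene has another one, 3 did. Those 17 are probe sets, not genes, and Nipal1 is counted once for each of its called plain probe sets. A low share among the _f_at genes had been written down beforehand as speaking for shared probes, but the plain probe sets gave a share as low, so that value does not separate the explanations. No biological explanation was tested for this pattern.

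Higher in TgSREBP-1a than in TgSREBP-2 were also Ppp1r3g (1.78), Fyb2 (1.53), Fads2 (1.47), Sult1e1 (1.37), Gramd3 (1.21, against a low signal of 3.06), the probe set 136586_at shared by Gm5637 and Arpc1b (1.2), Abca5 (1.15), Hephl1 (1.07), Acpp (1.01), Vnn1 (0.99), Dnase1l3 (0.92) and Gstm1 (0.76). Lower were Sdr9c7 (-3.23), 168288_f_at (-2.14), Slc3a1 (-1.66), 171596_at (-1.57), Kirrel3 (-1.36), Fads3 (-1.24), Smlr1 (-1.13), Serpina11 (-1.08), Nat8 (-1.04), Lbp (-0.88) and Klb (-0.59). The probe set 136586_at lost its call without any 1 of the 4 transgenic arrays (1.17, 1.23, 1.37 and 1.03), and 168288_f_at without TgSREBP-1a replicate 1 (-2.21), TgSREBP-1a replicate 2 (-2.07) or TgSREBP-2 replicate 1 (-1.83). Gstm1 lost its call without TgSREBP-1a replicate 1 (0.70) or TgSREBP-2 replicate 2 (0.66), and Gramd3 without TgSREBP-1a replicate 1 (1.19). Further probe sets of Gstm1 differed by -0.24 and 0.03.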

How the results depend on the processing

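The settings with the 18S rRNA signal, the crossed replicate pairing, cyclic loess and the count without acinar genes were chosen after seeing the data. None of the 84 values of named genes reversed under any alternative that gave it a value (29 with plain _at probe sets alone, 82 with brighter ones, 76 with arrays of the same study), and all 84 kept their calls under quantile normalisation, median centring, cyclic loess, a variance trend, no fold floor, the replicate block and the 18S rRNA covariate. Part of this was fixed in advance. The variance settings, treat and the fold floors leave the log2 differences as they are, so no sign could change there. Dropping the floor cannot lose a call. The largest increases and decreases were picked for arrays without overlap, so leaving out 1 array could not reverse them. With robust variance 7 lost the call, with a 2-fold floor 12, with treat 26, with arrays of the same study alone 5 of 76, and on leaving out 1 array 3 to 30. Array signal carries no counts, so depth is not known, and probe sets near the floor, such as Cpb1, say little. Where an array is left out, the lone array of its group is assumed to vary like the other groups.

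Counts of called probe sets are given in the order Scap-/-, TgSREBP-1a, TgSREBP-2, TgSREBP-1a against TgSREBP-2, and Scap wild type against SREBP wild type. They stayed within 1.5 times the reported counts under both scalings and cyclic loess, brighter probe sets, the variance trend, robust variance, no floor, and without acinar genes (8, 119, 12, 55 and 10). With plain _at probe sets alone they were 4, 67, 4, 36 and 5, and the count raised in both transgenics and lowered in Scap-/- was 0, because this setting leaves out the probe sets of its 3 genes. A 2-fold floor gave 59 for TgSREBP-1a and 31 between the transgenics, by its construction. Treat gave 6, 47, 9, 27 and 7, and arrays of the same study alone gave 4 for Scap-/-, with fewer arrays in the fit. The replicate block gave 19, 186, 37, 96 and 36, among them all of the 10, 123, 14, 61 and 11 reported. The replicate differences correlated positively in 7 of 10 pairs of groups (0.204 to 0.332) and negatively in 3 (-0.114, -0.171 and -0.175), and the labels name nothing that arrays of a number share, so the numbers were not taken as pairs. In all 5 groups, though, the 18S rRNA signal at the 3' probe set was higher in replicate 2 and Nsdhl, Pmvk, Tm7sf2 and Fads2 were higher in replicate 1, which leaves shared handling open. The 18S rRNA covariate gave 22 for TgSREBP-2 and 22 between the wild types, and the crossed pairing gave 111 between the transgenics, where 94 were called in the same 4 arrays without it. For these last settings the cause was not tested.

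On leaving out 1 array the counts ranged from 3 to 11, 40 to 134, 7 to 17, 23 to 65 and 3 to 10. The count raised in both transgenics and lowered in Scap-/- ranged from 1 to 3, and its mirror from 0 to 0. The correlation between the transgenic effects ranged from 0.459 (without TgSREBP-2 replicate 2) to 0.692 (without SREBP wild type replicate 1). The part that the shared wild type gives by itself also changes with the array left out. It was simulated for all 10 arrays alone, so this range does not show how far the effects themselves agree. The correlation of TgSREBP-1a with Scap-/- ranged from -0.0761 to 0.162 and that of TgSREBP-2 with Scap-/- from -0.134 to 0.0604. The latter correlations reversed, the first without Scap-/- replicate 1 (-0.0761) or Scap wild type replicate 2 (-0.0498) and the second without Scap-/- replicate 2 (0.0604) or Scap wild type replicate 1 (0.0326); the cause was not tested.

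Of the gene lists, 3, 2, 2, 1 and 4 were called. With an estimated correlation 0 were called in each of the 5 comparisons, where the test allows for correlation between a list's genes. With the mean over the probe sets of a gene, 4 were called in TgSREBP-2 and 0 between the transgenics; the cause was not tested. On leaving out 1 array the lists called ranged from 1 to 3, 2 to 4, 1 to 3, 0 to 1 and 0 to 5.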

Other observations

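The wild-type pools of the 2 studies differed in the sterol synthesis genes Nsdhl and Pmvk, the interferon regulator Irf7 and the hormone gene Fgf21. Diet, age, injections, strain and study differ together between them, so that no difference can be assigned to one of these. Nsdhl was 5.72-fold higher in Scap wild type (log2 difference 2.52, SE 0.279, adjusted p = 0.00681) and Pmvk 2.52-fold (1.33, adjusted p = 0.0104; 0.20 at its second probe set), and of the 13 cholesterol genes 2 rose and 3 did when adjusted over the list alone, with 1 lower (list adjusted p = 0.0911). Both genes lost their calls without Scap wild type replicate 1 (2.27 and 1.21) or SREBP wild type replicate 2 (2.21 and 1.07). Irf7, a regulator of interferon genes, was 3.59-fold higher (1.84, adjusted p = 0.00174) and was the 1 called member of the 13 interferon genes, a list that was higher than other genes (adjusted p = 0.0155; adjusted p = 0.529 with an estimated correlation). Rnf213 (1.69) and Serpina12 (1.47) were higher too, as were 2 probe sets of the skeletal muscle gene Myom2 (1.92 and 2.05, with 0.06 at a brighter one) and 1 of Hsd17b2 (1.11, with 0.15 and -0.52 at others).

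The hormone gene Fgf21 was lower in Scap wild type (-0.88, adjusted p = 0.0081). It is 1 of the 5 measured members of the fatty acid oxidation and ketogenesis list, with Plin2, Vnn1, Hadhb and Hsd17b4. That list was lower than other genes (adjusted p = 0.00187, and adjusted p = 0.213 with an estimated correlation). The list of lipoproteins and lipid droplets was lower without a called member (adjusted p = 0.0155; adjusted p = 0.281 with an estimated correlation), and that of macrophage markers was higher without one (adjusted p = 0.0391; adjusted p = 0.281 with an estimated correlation). Cpa1 (-1.50) and Kif21a (-0.83) were lower. Over all probe sets 8 were higher and 3 lower, against 862 at an unadjusted p under 0.05. The count was 36 with the replicate number as a block, 22 with the 18S rRNA signal as a covariate, 7 with treat and 5 with plain _at probe sets alone. It was 3 without Scap wild type replicate 1 and 7 without SREBP wild type replicate 2 or either TgSREBP-2 array. Fgf21 lost its call without any 1 of the 4 wild-type arrays (range over all alternatives -0.89 to -0.84), and Cpa1 without Scap wild type replicate 1 (-1.50) or 2 (-1.51). Kif21a lost its call without either Scap wild type array, SREBP wild type replicate 1 or any TgSREBP-1a or TgSREBP-2 array (-0.99 to -0.68), and Rnf213 without Scap wild type replicate 1 or any 1 of the 6 arrays of the other study (1.30 to 2.08).

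None of the 21 measured cell cycle genes was called in TgSREBP-1a (list adjusted p = 0.0812). Likewise, none of the 4 measured hepatocyte markers was called in Scap-/-, TgSREBP-1a or TgSREBP-2 (list adjusted p = 0.768, 0.516 and 0.169). Among these markers, Ahsg and Serpina1a had low mean signals over the arrays (log2 2.86 and 3.43). Their values say little, so the list test does not show that hepatocyte content was unchanged.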
